A study of Arabidopsis thaliana with 8 samples.

How the data were processed

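Total RNA from Arabidopsis thaliana seedlings was labelled with biotin and hybridised to Affymetrix arrays, 1 array per sample, per the labels. The 8 samples were grouped by their titles into wild type (Col-0) and til1-1, each at 22 °C and 37 °C, with 2 biological replicates per group and about 100 plants per pool. The deposited table holds 1 linear intensity value for each of 22810 probe sets on each array. These intensities were made by the authors with GCOS, the Affymetrix software, per the submitters' processing notes, which give no version; the summary algorithm and its settings are not given in the sources used here. In the deposited intensities, the mean after leaving out 2% of values at each end was 500.04 or 500.05 on every array, so the arrays had been scaled to a common trimmed mean. Such scaling sets the mean and not the median: array medians were lower after heat shock by 0.32 (wild type) and 0.31 (samples labelled til1-1) on the log2 scale. The mean of 9 spiked control probe sets (bio and cre) was higher after heat shock by 0.46 in each genotype. Nothing used here shows that these controls track the RNA of the seedlings, so scaling to them gives no measure of its amount. No background or detection call accompanied the values used here, and arrays of this kind have no read depth; their number limits the precision.

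Probe sets were named from the platform annotation supplied with the values, with symbols updated by gene ID from a table of the TAIR10.1 assembly. Of the 22810 probe sets, 64 were controls, 13513 were paired with 1 gene, 503 with several genes and 8730 were unlisted; 13436 of the 1-gene probe sets matched the table by gene ID. Only probe sets paired with 1 gene were named as genes, and an unlisted probe set is unnamed here, not without a gene. Where a gene had several such probe sets, lists used the one with the highest mean. Of 110 genes with at least 2 tested probe sets, 4 had probe sets called in opposite directions by heat shock. No coordinates were used.

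Intensities were transformed to log2(intensity + 16), so that a log2 fold change of a dim probe set understates its change in intensity. Controls were left out, then the 25% of probe sets with the lowest mean, which left 17059. Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 8 samples, 4 residual degrees of freedom, empirical Bayes moderation with an intensity trend, and Benjamini-Hochberg adjustment over all tested probe sets at a threshold of 0.05. All 4 groups shared 1 estimate of the spread, although the median SD between replicates was 0.07 and 0.09 at 22 °C and 0.12 and 0.12 at 37 °C. Every adjusted p-value of a single probe set is from this test. The 5 comparisons were heat shock in each genotype, samples labelled til1-1 against wild type at each temperature, and the difference of the heat shock responses. Errors of log2 values are standard errors from limma, and SDs are over the 2 samples of a group.

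Gene lists were tested with camera in limma, two-sided, with a preset correlation of 0.01 between genes and, as an alternative, an estimated one. The 22 lists with 395 members were written from general knowledge before the data were examined, as were the design, the rule for named genes and the alternatives, except where a choice is said to have been made later. Only 71 of the 395 members had a probe set paired with 1 gene, and 65 of these were tested. Lists for heat shock factors, for fatty acid desaturases and tocopherol synthesis, and for flavonoid synthesis had no measured member. The standard heat shock reporters that the rule asked for, such as HSFA2 and HSP101, had no probe set paired with 1 gene and were not analysed here by name. A minimum of 3 measured members for a set test was chosen after the annotation was seen and left 10 lists and 50 tests, adjusted together; 18 passed with the preset correlation and 2 of these, small heat shock proteins in both heat comparisons, also with an estimated correlation. The estimate was 0.00119 for small heat shock proteins, -0.154 for cell wall loosening and -0.239 for oxidative stress genes. These lie under the preset 0.01, so a higher correlation did not raise the p-values of these lists. The camera adjusted p of small heat shock proteins in wild type still went from 1.47e-11 to 0.0489. The 2 forms of the test thus differ in more than the correlation used, and a pass lost with the estimate is no measure of correlation. Cell wall loosening and oxidative stress genes, which did not pass with an estimated correlation, are thus not shown to owe their pass to correlated members. The estimate was above the preset for photosynthesis genes (0.565), root-enriched genes (0.48), the unfolded protein response (0.36) and large chaperones (0.261). Correlated members may have lowered the p-values of these lists with the preset. By fry, which asks whether the members of a list move on balance one way, 19 passed. TIL is a member of 2 lists.

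The rule for named genes took TIL always and, in each comparison, the 10 largest rises and 10 largest falls among called probe sets of 1 gene whose 2 groups did not overlap. Where fewer than 5 passed, the 5 smallest p-values were named as not passed. From each list, up to 4 called members with the largest change were named; further members are given to describe the list and were added after the values were seen.

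The limma step was checked on 5 sets of simulated arrays of 17059 probe sets, each with 200 changed. In the comparison of genotypes at 22 °C it recovered 82.2% of 2-fold and 98.0% of 4-fold changes, and 7.11% of its calls were false. At 37 °C it recovered 82.4% and 98.2%, with 7.67% false, and for the difference of responses 69.5% and 91.8%, with 5.98% false. Camera called 5 of 5 simulated sets of 10 raised members and 0 of 5 unchanged sets. The simulated noise was independent between probe sets and had the same spread in all groups. The shares recovered hold for that number of changed probe sets. False calls from correlated members could not arise there, whereas the photosynthesis list had an estimated correlation of 0.565. The 5 unchanged sets are too few for an error rate. Alternatives covered the added constant, the filter, the scaling between arrays, the intensity trend, the samples in the fit, a replicate block, other set tests and leaving out each sample in turn. Scaling to the spiked controls was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No sample was left out of the results given as main values.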

Results

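Transcript levels were measured on Affymetrix arrays in 7-day-old seedlings of Arabidopsis thaliana, in wild type (Col-0) and in til1-1, a mutant of the gene for temperature-induced lipocalin (TIL, AT5G58070). TIL is a small membrane-associated protein of the lipocalin family, whose members bind lipids and other hydrophobic molecules. Each sample was RNA from a pool of about 100 plants, kept at 22 °C or collected directly after heat shock at 37 °C. The duration of the heat shock is not given in the sources used here. The 8 samples formed 4 groups of 2 biological replicates, 1 group for each combination of genotype and temperature. Each array held 22810 probe sets, and the small number of arrays limits the precision of every value. The median intensity of an array was 197.4 to 204 at 22 °C and 154.75 to 160.15 at 37 °C, in the arbitrary units of the deposited table.

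Temperature separated the samples far more than genotype did. Across probe sets, which are not independent replicates, the Pearson correlation of log2 intensity was 0.978 to 0.991 between replicates and 0.978 to 0.991 between genotypes at the same temperature. Between temperatures it was 0.882 to 0.897. The first principal component held 82.2% of the variance and placed the 4 samples at 22 °C apart from the 4 at 37 °C.

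The targeted gene was examined first. The TIL probe set read 3464 ± 469 (SD, n = 2) in wild type at 22 °C and 3108 ± 84.7 (SD, n = 2) in the samples labelled til1-1 at 22 °C. The log2 difference between them was -0.15, with a 95% confidence interval of -0.35 to 0.05. At 37 °C TIL reached 20768 ± 676 (SD, n = 2) in wild type and 5573 ± 327 (SD, n = 2) in the samples labelled til1-1. TIL thus separated the genotype labels at 37 °C in all 4 samples, and at 22 °C its level did not bear out the label. Where its probes lie relative to the mutation is not given in the sources used here, and a probe set outside the altered part of the gene would check nothing. For that reason the mutant samples are called samples labelled til1-1 throughout.

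**Figure D1:**
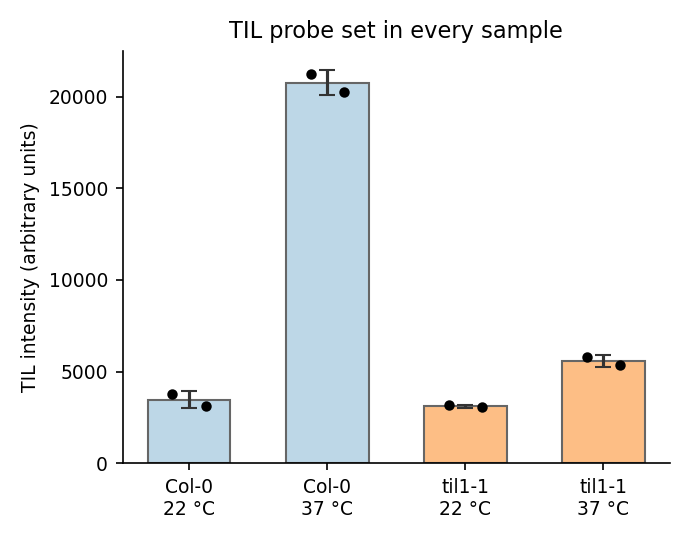
Intensity of the TIL probe set in arbitrary units (vertical axis, from 0) in the 4 groups of 2 samples; bars are means, error bars are SD and points are samples. Wild type at 37 °C averaged 20768, against 5573 in the samples labelled til1-1 at 37 °C, while both groups at 22 °C lay near 3464 and 3108.

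The first comparison asked which transcripts heat shock changed in wild type. Small heat shock proteins, chaperones that bind unfolding proteins, were prominent among the largest rises. HSP17.6C (AT1G53540) went from 9.85 ± 7.00 (SD, n = 2) to 28692 ± 1322 (SD, n = 2) intensity units, a log2 fold change of 10.14 ± 0.15 (standard error). Among the falls was that of AT5G54370 (from 907 to 65.0 intensity units, log2 fold change -3.53 ± 0.23). TIL itself rose 6.0-fold (log2 fold change 2.58 ± 0.09). All these changes passed limma at Benjamini-Hochberg adjusted p-values from 8.22e-14 to 1.9e-07.

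Among the 10 genes named for their rises in wild type, 7 encode small heat shock proteins. Besides HSP17.6C these were HSP26.5 (AT1G52560, log2 fold change 10.03), HSP22.0 (AT4G10250, 9.57), HSP17.6B (AT2G29500, 8.06), HSP15.7 (AT5G37670, 7.42), HSP23.5 (AT5G51440, 7.15) and HSP17.4B (AT1G54050, 7.05). The other 3 were AT1G71000 (8.87) and AT2G20560 (7.38), which encode DnaJ-domain co-chaperones, and HOP3 (AT4G12400, 7.36), an HSP70-HSP90 organizing protein. Several of these started near the lower end of the scale, where the added constant of 16 makes a log2 fold change understate the change in intensity, and their order depends on that constant. The 10 named falls, whose order depends on that constant too, held the pectin methylesterase gene AT2G47550 (-2.74), the peroxidase genes AT5G64110 (-2.67) and AT2G18980 (-2.64), the beta-glucosidase gene BGLU33 (-3.04) and the aspartyl protease gene AT3G61820 (-2.63). The remaining falls were AT5G10130 (-3.05), AT1G28400 (-2.81), the receptor kinase gene AT3G28040 (-2.72) and AT5G61570 (-2.54). AT5G64110 lies beside close relatives whose transcripts may share its probes, so its value is uncertain.

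Of the small heat shock proteins fixed as a list, 10 were measured and 8 rose, with a median log2 fold change over the list of 7.29. The smallest of these 8 rises was HSP18.5 (AT2G19310) at 4.02, while HSP15.4 (-0.04) and HSP21.7 (-0.12) did not pass. The list stood above other genes by camera at an adjusted p of 1.47e-11, and at an adjusted p of 0.0489 with an estimated correlation. Among 6 large chaperones and co-chaperones, 5 rose: HOP3, ROF2 (AT5G48570, 6.61), the cytosolic HSP70 genes HSC70-3 (3.47) and HSC70-2 (2.67), and HOP2 (2.59), whereas HOP1 (0.06) did not pass. The camera adjusted p was 3.66e-08, against an adjusted p of 0.2 with an estimated correlation. HSA32 (5.78), a heat-induced protein needed for acquired thermotolerance, rose as well; with TIL it made up the 2 measured members of a list of other thermotolerance genes.

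In the unfolded protein response of the endoplasmic reticulum, 3 of 6 measured genes rose. These were DER1 (2.91), which acts in the removal of misfolded proteins, and the transcription factor genes BZIP28 (1.66) and BZIP60 (0.43); CNX2 (0.29), ERDJ3B (0.10) and CRT1B (-0.12) did not pass. The camera adjusted p of this list was 0.00584, and the adjusted p was 0.351 with an estimated correlation. Of 4 genes known to respond to oxidative stress, 3 rose: ZAT10 (also STZ, 3.22), a zinc finger repressor, UPOX (AT2G21640, 0.90) and AT12CYS-2 (0.84), with GSTU25 (-0.12) not passing. Here the camera adjusted p was 0.0495, and the adjusted p was 0.351 with an estimated correlation. Among 5 enzymes that scavenge reactive oxygen, GR2 rose (0.26) and MDAR2 fell (-0.34), while TAPX (0.14), SAPX (-0.21) and GR1 (0.16) did not pass (camera adjusted p 0.572). In the list for abscisic acid, dehydration and cold, the dehydrin genes COR47 (1.68) and LTI30 (0.88) rose, and COR15A (-0.44) and COR15B (-0.08) did not pass (camera adjusted p 0.0827).

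Nuclear genes of photosynthesis shifted little: 6 of 7 rose, with a median log2 fold change of 0.30, the highest being PSAE-1 (0.42), LHCB4.1 (0.39) and RCA, rubisco activase (0.37), with LHCB4.2 (0.17) not passing. Their camera adjusted p was 0.00452, the adjusted p was 0.358 with an estimated correlation, and their direction depended on the scaling of the arrays, with a median of -0.24 after quantile normalization and -0.16 after scaling to spiked controls. All 3 measured genes of cell wall loosening fell, namely the expansin genes EXPA4 (-2.02), EXPA15 (-2.01) and EXPA8 (-1.58), with a camera adjusted p of 0.0213 and an adjusted p of 0.351 with an estimated correlation. Root-enriched genes, listed as markers of a tissue whose share of the sample could differ, fell in 3 of 3 cases: EXPA7 (-1.20), EXPA18 (-1.19) and the beta-glucosidase gene PYK10 (-0.67), at a camera adjusted p of 0.0601. Of 3 auxin response genes, GH3.3 (0.82) and GH3.5 (0.69) rose and IAA29 (0.14) did not pass (camera adjusted p 0.0906).

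Further lists had 1 or 2 measured members in wild type. MCM7 (-0.37) fell and AUR1 (0.04) did not pass for the cell cycle; PES (-0.27) fell and RPL4A (-0.12) did not pass for ribosomes. Of the reference genes, SAND (-0.81) fell and TIP41 (-0.06) did not pass. The chloroplastic lipocalin CHL (-0.04), GI of the clock (-0.04), PDF1.2 of the jasmonate response (0.23), SAG101 of defence (0.15) and ICL of seedling establishment (0.38) did not pass. In each list the count adjusted over the list alone was the one over all probe sets.

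In the same comparison the 25S rRNA control probe set rose 7.37-fold, and the ratio of the 3' to the 5' actin control probe sets went from 1.74 ± 0.01 (SD, n = 2) to 2.01 ± 0.21 (SD, n = 2). The same ratio went from 1.16 ± 0.03 to 1.09 ± 0.04 for ubiquitin and from 1.00 ± 0.002 to 0.997 ± 0.056 for GAPDH (SD, n = 2). Heat shock in wild type changed 7461 of 17059 tested probe sets at a limma adjusted p under 0.05, of which 2118 were higher and 5343 lower. Of these, 689 were higher and 1495 lower by at least 2-fold. The split depended on the scaling of the arrays: higher calls made up 28.4% as deposited, 66.7% with array medians set equal, 40.7% after quantile normalization and 6.5% after scaling to the spiked controls, where 12213 probe sets were called. The median of all tested probe sets moved with it, from -0.18 as deposited to 0.14, -0.05 and -0.64 on the log2 scale. Called in the same direction under all 4 scalings were 793 higher and 2485 lower probe sets, and of the genes named above as changed, BZIP60, GR2, PSAE-1, LHCB4.1 and RCA turned negative after scaling to spiked controls, the last 3 also after quantile normalization, and PES turned positive with medians set equal. The falls of MDAR2 and MCM7 did not pass with medians set equal, nor the fall of MCM7 and the rise of GR2 after quantile normalization, nor the rises of UPOX, AT12CYS-2, GH3.3 and GH3.5 after scaling to spiked controls. As lists, oxidative stress genes did not pass with medians set equal or after quantile normalization, nor cell wall genes after scaling to spiked controls.

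**Figure D2:**
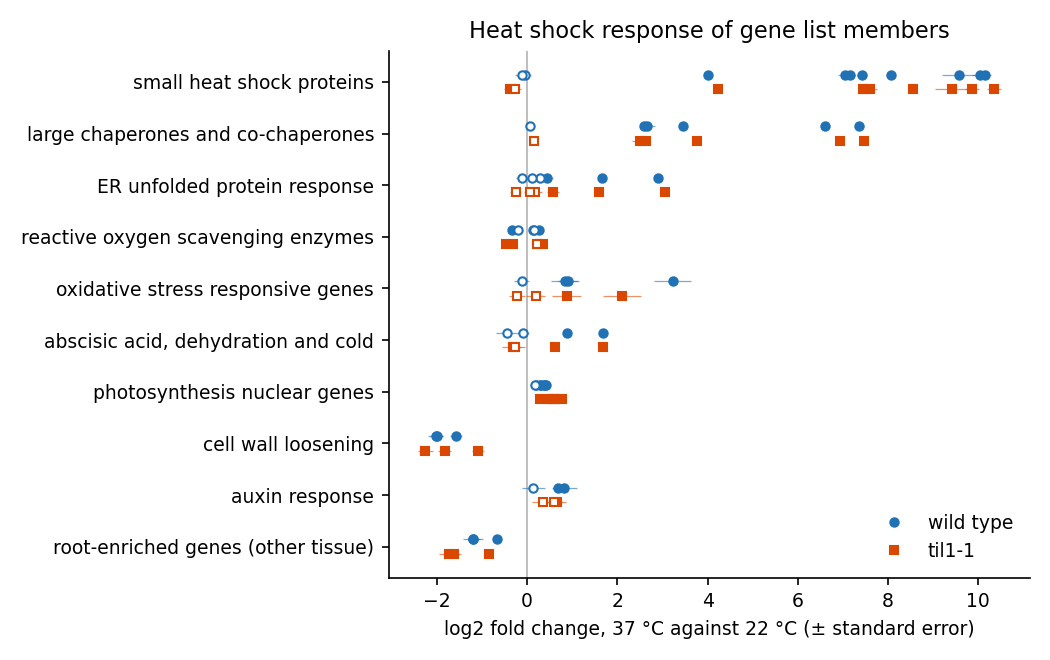
Log2 fold change of 37 °C against 22 °C (horizontal axis) for each measured member of the 10 gene lists with at least 3 such members, in wild type (circles) and in samples labelled til1-1 (squares); filled symbols passed limma at an adjusted p under 0.05, open symbols did not, and bars are standard errors. Small heat shock proteins reached 10.14 in wild type and 10.35 in the samples labelled til1-1, while the 3 cell wall loosening genes lay between -2.25 and -1.09 over both genotypes; values of photosynthesis genes turn negative under some scalings.

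The second comparison asked for the same response in the samples labelled til1-1. The same small heat shock proteins were prominent: HSP17.6C rose from 9.50 ± 2.55 (SD, n = 2) to 33100 ± 52.6 (SD, n = 2) intensity units, a log2 fold change of 10.35 ± 0.15. HSP26.5 rose by 9.86 on the log2 scale, with HSP22.0 at 9.41, the DnaJ gene AT1G71000 at 9.07 and HSP17.6B at 8.54. TIL rose 1.79-fold (log2 fold change 0.84 ± 0.09, limma adjusted p 1.43e-05). Among the falls were AT5G54370 (-3.38) and the peroxidase gene AT5G64120 (-3.26).

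The rest of the 10 named rises in the samples labelled til1-1 were HSP17.4B (7.59), HSP23.5 (7.47), HOP3 (7.46), HSP15.7 (7.44) and AT2G20560 (7.07). Falls continued with AT5G10130 (-3.24), the peroxidase gene AT5G64110 (-2.94), the protease gene AT3G61820 (-2.84), the dirigent gene AT4G13580 (-2.81) and the pectin methylesterase gene AT1G02810 (-2.72). BGLU33 (-2.70), AT4G28240 (-2.70) and AT1G28400 (-2.66) completed them. AT5G64110 and AT5G64120 are neighbouring peroxidase genes of similar sequence, and signal shared between them cannot be excluded.

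In the samples labelled til1-1, 8 of 10 small heat shock proteins rose and HSP15.4 fell (-0.38), a fall that did not pass with array medians set equal (-0.06); HSP21.7 (-0.26) did not pass. The list median was 7.53, with a camera adjusted p of 9.5e-11 and an adjusted p of 0.0489 with an estimated correlation. Large chaperones rose in 5 of 6 cases, as ROF2 (6.93), HSC70-3 (3.77), HOP2 (2.64), HSC70-2 (2.50) and HOP3, with HOP1 (0.14) not passing. That list had a camera adjusted p of 2.15e-08 and an adjusted p of 0.2 with an estimated correlation. HSA32 rose by 5.83. DER1 (3.06), BZIP28 (1.60) and BZIP60 (0.57) were the 3 of 6 endoplasmic reticulum genes that rose, with a camera adjusted p of 0.0113 and an adjusted p of 0.351 with an estimated correlation.

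Oxidative stress genes rose in 2 of 4 cases in the samples labelled til1-1, ZAT10 (2.11) and AT12CYS-2 (0.88), with UPOX (0.19) and GSTU25 (-0.23) not passing (camera adjusted p 0.181). Among the scavenging enzymes TAPX rose (0.35), a value of -0.11 after scaling to spiked controls, and SAPX (-0.46) and MDAR2 (-0.32) fell (camera adjusted p 0.552); adjusted over the list alone, GR1 (0.22) and GR2 (0.22) also passed. COR47 (1.69) and LTI30 (0.62) rose, and COR15A (-0.30) and COR15B (-0.27) did not pass (camera adjusted p 0.135). All 7 photosynthesis genes rose, with PSAE-1 (0.78), RCA (0.62) and LHCB4.1 (0.62) highest and a list median of 0.57, which was -0.15 after quantile normalization. Their camera adjusted p was 0.000104, and the adjusted p was 0.351 with an estimated correlation. The expansin genes EXPA4 (-2.25), EXPA15 (-1.83) and EXPA8 (-1.09) fell, with a camera adjusted p of 0.0293 and an adjusted p of 0.351 with an estimated correlation. Root-enriched EXPA7 (-1.73), EXPA18 (-1.61) and PYK10 (-0.84) fell, with a camera adjusted p of 0.032 and an adjusted p of 0.351 with an estimated correlation. GH3.5 was the auxin gene that rose (0.67), with GH3.3 (0.59) and IAA29 (0.36) not passing (camera adjusted p 0.0903).

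For the shorter lists in the samples labelled til1-1, MCM7 (-0.55), PES (-0.44), RPL4A (-0.24) and SAND (-0.64) fell. RPL4A was at 0.08 with array medians set equal, where the falls of MCM7, PES, SAPX and MDAR2 did not pass either; that of MCM7 did not pass after quantile normalization. After scaling to spiked controls, the rises of BZIP60, AT12CYS-2, LTI30, GH3.5, LHCB4.1 and RCA did not pass, nor did the cell wall and root-enriched genes as lists. AUR1 (-0.13), TIP41 (0.01), CHL (0.14), GI (0.07), PDF1.2 (-0.20), SAG101 (0.06) and ICL (-0.17) did not pass.

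The 25S rRNA control rose 8.49-fold in the samples labelled til1-1, and the actin 3' to 5' ratio went from 1.65 ± 0.12 (SD, n = 2) to 2.08 ± 0.06 (SD, n = 2). For ubiquitin it went from 1.19 ± 0.05 to 0.992 ± 0.142 and for GAPDH from 0.952 ± 0.053 to 1.02 ± 0.03 (SD, n = 2). Limma called 7563 probe sets, 2174 higher and 5389 lower, with 674 higher and 1504 lower by at least 2-fold. Higher calls made up 28.7% as deposited, 65.5% with array medians set equal, 40.4% after quantile normalization and 6.4% of 12403 calls after scaling to spiked controls. Under all 4 scalings, 776 probe sets were called higher and 2569 lower.

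The heat shock responses of the genotypes were then set side by side. Over 17059 probe sets, the log2 fold changes of the genotypes correlated at a Pearson r of 0.926 and a Spearman rho of 0.830, across probe sets and without independent replicates. Of the probe sets called higher, 1685 were shared, where independent lists of these sizes would share 269.9. Of those called lower, 4198 were shared, against 1688 for independent lists. In opposite directions 2 probe sets were called. The responses share no arrays, so no shared control raised these values. Both used the same estimate of the spread for each probe set, and array medians shifted alike with heat shock (-0.32 and -0.31). Shared calls may for these reasons exceed those of independent lists.

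**Figure D3:**
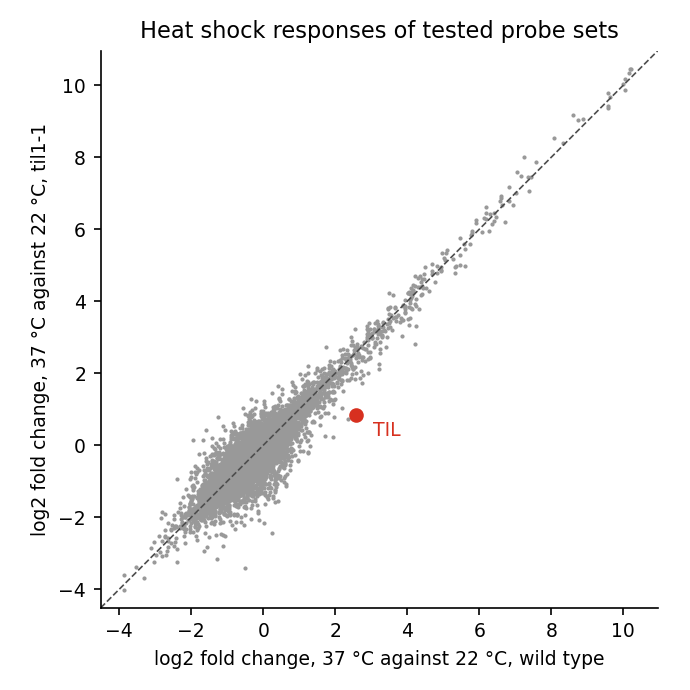
Log2 fold change of 37 °C against 22 °C in wild type (horizontal axis) and in samples labelled til1-1 (vertical axis) for each tested probe set (grey points), with the line of equal response dashed and TIL in red. The points follow the line (Pearson r 0.926), and TIL lies under it at 2.58 and 0.84.

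The third comparison asked whether the samples labelled til1-1 differed from wild type at 22 °C. No named gene passed. Probe set 267083_at, which the annotation used here pairs with no gene, was the 1 call: it read 2702 ± 173 (SD, n = 2) in wild type and 4203 ± 183 (SD, n = 2) in the samples labelled til1-1, a log2 difference of 0.64 ± 0.07 (limma adjusted p 0.0288). It lies outside the rule for named genes and is given because it was the single call, after its values were seen. The 5 named genes of smallest p-value did not pass: AT2G18690 (0.70), AT4G21580 (0.42), AT1G72900 (0.66), AT2G07676 (1.17) and AT3G14200 (-0.60), with limma adjusted p-values of 0.645 to 0.772.

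Gene lists at 22 °C differed little between genotypes. Root-enriched genes lay lower in the samples labelled til1-1 by camera, at a median of -0.26 (adjusted p 0.0295), with EXPA7 (-0.29), EXPA18 (-0.26) and PYK10 (-0.11) not passing singly; the adjusted p was 0.351 with an estimated correlation, and the list did not pass after quantile normalization or scaling to spiked controls. Cell wall loosening genes lay lower as a list, at a median of -0.23 (camera adjusted p 0.0321), with EXPA15 (-0.24), EXPA4 (-0.23) and EXPA8 (-0.20) not passing; the adjusted p was 0.351 with an estimated correlation. Photosynthesis genes had a median of -0.11 (camera adjusted p 0.0514) and oxidative stress genes one of 0.26 (camera adjusted p 0.11). The other tested lists had camera adjusted p-values of 0.341 to 0.908. ROF2 (-0.31) passed when adjusted over the list alone. ICL (-0.56), the only measured member of its list, passed by limma without adjustment only.

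Over all probe sets, 656 (3.85%) had an unadjusted p under 0.05 by limma. The 95% confidence interval of the difference lay within 1 log2 unit of 0 for 92.8% of the probe sets. On simulated arrays with 200 changed probe sets, 82.2% of 2-fold changes were recovered. With fewer true changes the adjustment is stricter, so that share does not hold for a difference in few genes. The call of 267083_at was lost without the filter on dim probe sets, without the intensity trend, with the fit limited to the 2 groups, and without any 1 of the 8 samples. Scaling to spiked controls gave 3 calls, 267083_at among them.

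After heat shock, the fourth comparison found TIL as the named gene that differed. TIL was 3.72-fold lower in the samples labelled til1-1 than in wild type (log2 difference -1.90 ± 0.09, limma adjusted p 1.51e-06). Probe set 264684_at, unpaired with a gene in the annotation used here, read 25.1 ± 0.64 (SD, n = 2) in wild type and 130.7 ± 6.93 (SD, n = 2) in the samples labelled til1-1, a log2 difference of 1.84 ± 0.23 (limma adjusted p 0.0324). It too was named after its values were seen. This call was lost without the filter on dim probe sets, with the lowest 50% left out, with only the 2 groups compared, without replicate 2 of either heat-shocked group and without any 1 of the 4 samples at 22 °C; its log2 difference was 2.34 with an added constant of 1 and 1.13 with one of 64. Next by p-value, without passing, came AT5G01750 (0.43), the protein phosphatase gene PIA1 (-0.52), the plastid-encoded psbM (0.39) and the peroxidase gene AT5G64120 (-1.13), with limma adjusted p-values of 0.0956 to 0.103.

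Small heat shock proteins (median 0.16) and large chaperones (median 0.06) had no member whose difference between genotypes passed at 37 °C. Their camera adjusted p-values were 0.573 and 0.418. Root-enriched genes lay lower in the samples labelled til1-1 at a median of -0.68 (camera adjusted p 0.00102), and the adjusted p was 0.351 with an estimated correlation. EXPA7 (-0.82), EXPA18 (-0.68) and PYK10 (-0.28) did not pass over all probe sets, and all 3 passed adjusted over the list alone. Photosynthesis genes lay higher at a median of 0.16 (camera adjusted p 0.0448), with an adjusted p of 0.533 with an estimated correlation; the list did not pass after quantile normalization or scaling to spiked controls. None of the 7 passed over all probe sets, and 3 passed adjusted over the list alone, led by PSAE-1 (0.25). EXPA4 (-0.46) passed adjusted over the list alone. ICL (-1.11), the only measured member of its list, passed by limma without adjustment only. The other tested lists had camera adjusted p-values of 0.545 to 0.954.

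In this comparison 2279 probe sets (13.4%) had an unadjusted p under 0.05 by limma, and 88.8% had a 95% confidence interval within 1 log2 unit of 0. Both values use the spread shared by all groups, although the median SD between replicates was 0.12 in both groups at 37 °C. At 22 °C it was 0.07 and 0.09. The share of 13.4% may thus be too high, and it cannot be set directly against the 3.85% at 22 °C. The count of 2 depended on the model and the scaling, being 10 without the intensity trend and 9 after scaling to spiked controls. It also depended on single samples: it was 16 without replicate 1 and 10 without replicate 2 of the heat-shocked samples labelled til1-1, 12 without replicate 1 of heat-shocked wild type, and 1 without any 1 of the 4 samples at 22 °C, with TIL among the calls each time.

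The fifth comparison tested the difference of the heat shock responses. TIL was the 1 probe set whose response differed: its rise was smaller by 1.75 ± 0.13 on the log2 scale in the samples labelled til1-1 (-1.75, limma adjusted p 0.000204). Without passing, the next named genes were the plastid-encoded rpl36 (-0.63), PIA1 (-0.56), AT5G35680 (-0.49) and AT3G56270 (-2.18), with limma adjusted p-values of 0.552 to 0.6. ZAT10 rose by 3.22 in wild type and 2.11 in the samples labelled til1-1, and its difference of -1.12 ± 0.59 did not pass (limma adjusted p 0.782). UPOX, called in wild type alone, had a difference of -0.71 ± 0.30 that did not pass either (limma adjusted p 0.717).

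Photosynthesis genes had a higher response as a list in the samples labelled til1-1, by a median of 0.25 (camera adjusted p 0.00565), which was 0.14 and did not pass after quantile normalization, where all 7 had negative responses in both genotypes. The adjusted p was 0.358 with an estimated correlation; 5 of 7 passed adjusted over the list alone, led by PSAE-1 (0.36) and PSBY (0.36). Root-enriched genes had a median difference of -0.42 (camera adjusted p 0.0305), and the adjusted p was 0.351 with an estimated correlation; 0 of 3 passed, over all probe sets or adjusted over the list alone, and the list did not pass after scaling to spiked controls. The chaperone genes ROF2 (0.32) and HSC70-3 (0.31) passed adjusted over the list alone. Lists for small heat shock proteins, large chaperones and oxidative stress had camera adjusted p-values of 0.399, 0.138 and 0.136, and the remaining lists of 0.422 to 0.953.

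By limma, 1156 probe sets (6.78%) had an unadjusted p under 0.05, and 77.4% had a 95% confidence interval of the difference within 1 log2 unit of 0. The call of TIL was lost in a fit without the intensity trend (adjusted p 0.106), where AT5G59700 (-1.90) was the 1 call, and it held in the other alternatives run.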

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

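In this part, the tests of a retained transcript, of a lower share of nuclear messenger RNA and of 3' bias were chosen only after the result was seen, as was the margin by which the correlation in the wrong-label test had to exceed the others; the criterion for 3' bias was relaxed after its result was seen. TIL drew attention because its heat shock response differed between the genotypes by test: the log2 difference, samples labelled til1-1 minus wild type, was -1.75. At 22 °C its signal in the samples labelled til1-1 was near that of wild type, at 3108 against 3464. If those samples at 22 °C were wild type under a wrong label, the genotype differences at 22 °C and 37 °C should be unrelated. They correlated at 0.0841, against a highest value of 0.0560 among the other 8 combinations of samples. For mixed combinations the sign can depend on an arbitrary choice of which samples are subtracted, and the highest absolute value was 0.0695. Either excess is smaller than the spread of the others (0.0485), and 9 combinations are too few for a share under 0.05. The criterion first written asked only for a value above every other combination, which 0.0841 met and which would have counted against a wrong label; the margin was added because so small an excess lies within the spread, so a wrong label stays open. A transcript that the mutation leaves and the probes read, which the difference of -1.75 cannot tell apart from a reduced induction of TIL by heat in the mutant, also stays open, because the places of the probes and of the mutation are not given in the sources used here.

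The 25S rRNA control probe set drew attention as a signal outside the comparisons: its log2 fold change with heat shock was 2.88 in wild type and 3.09 in the samples labelled til1-1, and mitochondrial transcripts rose with it (median 2.94 in wild type). A lower share of nuclear messenger RNA would raise plastid transcripts alike, but the mitochondrial median exceeded the plastid median by 2.45 in the genotype where they lay closer. Bright plastid probe sets, such as atpB at 23534 in wild type at 22 °C, may have had too little range left for so large a rise. The largest plastid rise in wild type was 0.85, in the dim rpoB (107 at 22 °C), and in the samples labelled til1-1 it was 1.30. Scaling of the arrays is argued against for the mitochondrial transcripts, whose smallest median was 2.49 over both genotypes with array medians set equal or arrays scaled to spiked controls. More 3' bias in the heat-shocked samples stays open: 1 of 3 control genes (actin) had a higher 3' to 5' ratio in every heat-shocked array, while that of ubiquitin was lower in each and that of GAPDH overlapped, which under the criterion first written (2 of the 3 not higher) counted against 3' bias. A change in mitochondrial RNA or in its labelling with heat may remain as a hypothesis, which was not tested.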

How the results depend on the processing

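Scaling to the spiked controls was the alternative chosen after the data were seen, and tests that use it were chosen only then. Where no reason is given, the cause was not tested. Arrays have no read depth, and values near the floor of the scale limit precision.

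The heat shock counts moved with this scaling to 12213 in wild type and 12403 in the samples labelled til1-1, and the shared calls to 10890. Leaving out 1 sample gave 5132 to 8058, 5536 to 7892 and 4400 to 5659; a group left with 1 sample was assumed to vary like the others. At 22 °C the count of 1 became 0 without the filter (more probe sets tested), 0 without the intensity trend, 0 with only the groups compared (fewer samples), 3 with spiked controls and 0 to 2 on leaving out 1 sample. At 37 °C the count of 2 became 1 without the filter, 1 with the lowest 50% left out, 10 without the trend, 1 with only the groups compared, 9 with spiked controls and 1 to 16 on leaving out 1 sample. For the difference of responses, leaving out 1 sample gave 1 to 2. The TIL difference was -1.88 to -1.52 over the settings that called it. Of 18 list tests, 2 passed with an estimated correlation.

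Pairing of replicates by number was checked by the correlation of replicate differences between groups, which was -0.04 to 0.14. A replicate block gave 3 calls at 22 °C and 15 at 37 °C, with AT5G01750, PIA1, psbM and AT5G64120 among the 15; the cause was not tested.

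Directions reversed for the following log2 fold changes with heat shock. With spiked controls, in wild type: HOP1 -0.40, BZIP60 -0.022, ERDJ3B -0.35, TAPX -0.31, GR2 -0.20, LHCB4.1 -0.066, PSAE-1 -0.038, PSAN -0.16, PSBW -0.17, PSBY -0.25, RCA -0.084 and AUR1 -0.42; in the samples labelled til1-1: HOP1 -0.32, ERDJ3B -0.41, TAPX -0.11, CHL -0.32, LHCB4.2 -0.011, PSBW -0.19, GI -0.39 and TIP41 -0.46. After quantile normalization, in wild type: LHCB4.1 -0.21, LHCB4.2 -0.28, PSAE-1 -0.17, PSAN -0.34, PSBW -0.23, PSBY -0.34, RCA -0.24 and the photosynthesis list -0.24; in the samples labelled til1-1: LHCB4.1 -0.15, LHCB4.2 -0.11, PSAE-1 -0.031, PSAN -0.19, PSBW -0.31, PSBY -0.064, RCA -0.18 and the list -0.15. With array medians set equal: CHL 0.29, GI 0.28, PES 0.051 and RPL4A 0.20 in wild type and RPL4A 0.078 in the samples labelled til1-1. The shift of every probe set by the scaling accounts for those with spiked controls and equal medians; for quantile normalization the cause was not tested.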

Other observations

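The organelle and gene family tests in this part were chosen only after the data were seen. Transcripts of the mitochondrial genome rose with heat shock in 20 of 22 tested probe sets in wild type and 21 of 22 in the samples labelled til1-1, among them nad6 (log2 fold change 6.58 in wild type). The 22 probe sets read 15 genes, since some, such as nad1, had more than 1. A nuclear chromosome of this species carries a near-identical copy of mitochondrial sequence, and the arrays do not separate the copies. Plastid transcripts had medians of 0.38 and 0.55, which became -0.04 and 0.07 after quantile normalization and -0.08 and 0.08 after scaling to spiked controls. With array medians set equal they were higher than as deposited, since that scaling removes shifts of -0.32 and -0.31 with heat shock.

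Of 34 gene families tested, alpha-expansins fell in 7 of 8 members in each genotype (medians -1.41 and -1.53; camera adjusted p 0.0207 in wild type, adjusted p 0.612 with an estimated correlation), and in 6 of 8 with array medians set equal. Of these members, EXPA7 and EXPA18 are also 2 of the 3 root-enriched genes that fell. EXPA4, EXPA15 and EXPA8 are the 3 measured cell wall loosening genes, so the family result is not separate from those lists. Serine carboxypeptidase-like genes fell in 13 of 17 members in each genotype (medians -0.76 and -0.81, camera adjusted p 0.041 in wild type). With array medians set equal they fell in 9 in wild type and 11 in the samples labelled til1-1, where 1 and 2 members rose. Calmodulin-like genes had a median response difference of -0.55 (camera adjusted p 0.0207), and no member's difference passed singly by limma. Among them, CML37 was at 4.04 in wild type and 3.33 in the samples labelled til1-1. Other families rose. The mitochondrial NAD genes, which are among the mitochondrial genes above, rose in 7 of 7 members in each genotype. The camera adjusted p was 6.59e-09 in wild type and 4.1e-09 in the samples labelled til1-1. ATG genes rose in 4 of 8 members in wild type (median 0.35, camera adjusted p 0.0207). In the samples labelled til1-1, 3 of 8 rose (median 0.26) and the family did not pass (camera adjusted p 0.117). A pass in 1 genotype alone does not show a difference between the genotypes. Both medians are smaller than 0.46, the shift of the spiked controls with heat shock, so this rise depends on the scaling. No family passed with an estimated correlation, where the lowest adjusted p was 0.612.

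More probe sets were called lower than higher after heat shock in the deposited scaling. If the scaling to a trimmed mean alone moved the bulk of probe sets down, equal array medians should give 40 to 60% lower calls; if not, over 60%. The share was 33.3% in wild type, outside both ranges, and 93.5% after scaling to spiked controls. Medians were set equal over all probe sets but controls, before the filter on dim ones. The tested probe sets were thus not centred, and neither range strictly follows for them. Nothing used here shows that the spiked controls track the RNA of the seedlings, so 93.5% is no measure of a loss of transcripts. No value here decides which scaling reflects that RNA. The majority direction may thus be a product of scaling or of heat shock, and these cannot be told apart.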
